A study of Homo sapiens with 6 samples.

How the data were processed

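ATAC-seq was done on 6 samples, the lines RS4;11, SEM and RCH each with NT or sh2. Per the labels' protocols, nuclei were tagmented with the Nextera enzyme and libraries were amplified by PCR with barcoded primers. Per the submitters' processing notes, the tools were Bowtie2 and MACS2 and the build was hg19. Versions, settings, removal of duplicates, shifting of reads for the transposase offset and read numbers are not given in the sources used here. Each sample came with 2 peak lists without headers, called separately as far as the lists show, with 5 columns (chromosome, start, end, name and a value). No peak ended past an hg19 chromosome end, and 5397 ended past a GRCh38 end.

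The value deposited by the authors with each peak was read as a fold enrichment, that is a ratio of the signal to the peak caller's background in the same library. This reading is inferred from the values. In each list 9.11% to 23.9% of the values were whole multiples (tolerance 0.0002) of 1 step, as a pileup plus 1 over a background plus 1 would give. The step gave a background level of 1.57 to 2.57, used as a stand-in for relative depth, which holds only if fragments were extended alike. True depth is unknown, so no depth-based floor was given. Folds were used to rank peaks within a list, to filter all lists at 1 pooled limit in the stricter setting, and to describe regions. They are not normalized between lists, so folds printed side by side for several libraries show no change in level. All lists ended below 3 kb, with peaks from 200 to 2937 bp, as an upper limit on width would leave them.

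Peaks on chromosomes 1 to 22 and X were used, which left out 140 peaks. Lists were merged into regions, joining peaks that touch or overlap, and a list counted as open in a region with an overlap of at least 1 bp. NT-only and sh2-only regions, crossed splits of the 4 lists of a line, Jaccard indices, and the across-line counts were fixed before the data were examined, as were the 1 Mb bins and the rule for named regions. That rule takes the 3 NT-only and the 3 sh2-only regions, over at least 2 lines, with the highest mean percentile of fold within their lists. The same ranking was also applied to regions changed in 3 lines, which the fixed rule did not name. The ranking of chromosomes by open regions per Mb, the distances, the odds ratios between lines, the line-specific regions, the search for stretches without peaks and the tests of explanations were chosen after the data were seen.

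Lines paired the samples in the across-line test, an exact two-sided sign-flip test over 3 lines. The pairing comes from the cell line named in the sample titles. Intervals of shares are exact binomial (Clopper-Pearson) at 95%, and odds ratios between lines are conditional with exact intervals. Those within classes of chromosome and distance (Mantel-Haenszel) and those of dense against sparse chromosomes (cross-products) have no interval. The limit for bins was the level that the most extreme bin stayed below in 95% of 1000 shuffles of the labels over the changed regions. The steps were tested on simulated lists built on the 98313 regions of RS4;11 with 200 regions gained and 200 lost. All planted regions were found (100%), beside 2258 unplanted gained and 2147 unplanted lost regions when lists were drawn independently. All simulated lists had the same chance of a peak in a region, namely the share of the real lists with a peak there. Regions that differ between NT and sh2 thus entered as variable ones, and neither unequal list length nor a detection limit was simulated. The unplanted counts show only that the rule also collects regions that vary between lists. The crossed splits measure such variation, but not a difference in depth or signal that both libraries of an shRNA share.

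Alternatives were lists of equal length (the peaks of highest fold, as many as in the shortest list of the line), only peaks above the median of pooled folds (6.37), coverage of 50% of a region, a distance of 1 kb from any peak of the other condition, 5 Mb bins, each library or line left out, and counts without pairing. Promoters, exon and intron shares, gene lists and 20 sequence motifs had been planned. They were not analysed here, since no hg19 annotation or sequence was used and coordinates were not converted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used, bedtools to check the merging.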

Results

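Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in 3 B-cell acute lymphoblastic leukemia lines carrying a non-targeting control shRNA (NT) or an shRNA against NSD2 (sh2). NSD2 is a histone H3 lysine 36 methyltransferase. RS4;11 and SEM carry a KMT2A-AFF1 fusion, and the line labelled RCH was taken to be the RCH-ACV of the growth protocol. Each of the 6 samples, 1 per line and shRNA, came with 2 peak lists, read here as 2 libraries. The labels do not say whether the 2 libraries came from separate cultures, so the spread between them may be technical. No test between NT and sh2 was possible within a line, and every interval over regions covers counting error only. After chromosome Y was set aside, the 12 lists held 718792 peaks on the 22 autosomes and X, from 41594 to 84794 per list. All coordinates are hg19. Genes were not assigned to regions, and NSD2 itself was not analysed here.

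The first comparison asked how much chromatin was called open with and without NSD2 knockdown. Fewer peaks were called after knockdown in RS4;11 and in RCH, and more in SEM. In RS4;11 the number fell from 79519 ± 7460 (SD, n = 2 libraries) with NT to 62472 ± 1302 with sh2, a change of -21.4%. In RCH it fell from 56800 ± 408 to 42919 ± 1874, a change of -24.4%, while the median fold enrichment of its peaks went from 6.10 ± 0.024 to 5.37 ± 0.067, the lowest of the 6 samples, and the background level from 1.78 ± 0.223 to 2.56 ± 0.014. In SEM it rose from 54455 ± 873 to 63233 ± 1368, a change of 16.1%. The NT and sh2 libraries did not overlap in number in any of the lines. Covered sequence moved the same way in these lines, from 34.2 to 26.6 Mb, from 23.1 to 17.6 Mb and from 24.9 to 27.7 Mb. The log2 ratio of peak number (sh2 over NT) was -0.35 in RS4;11, -0.40 in RCH and 0.22 in SEM, with a mean of -0.18 ± 0.34 (SD, n = 3 lines, exact two-sided sign-flip test, p = 0.5, where the smallest possible p is 0.25). With 3 lines no common effect on peak number could be shown.

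**Figure D1:**
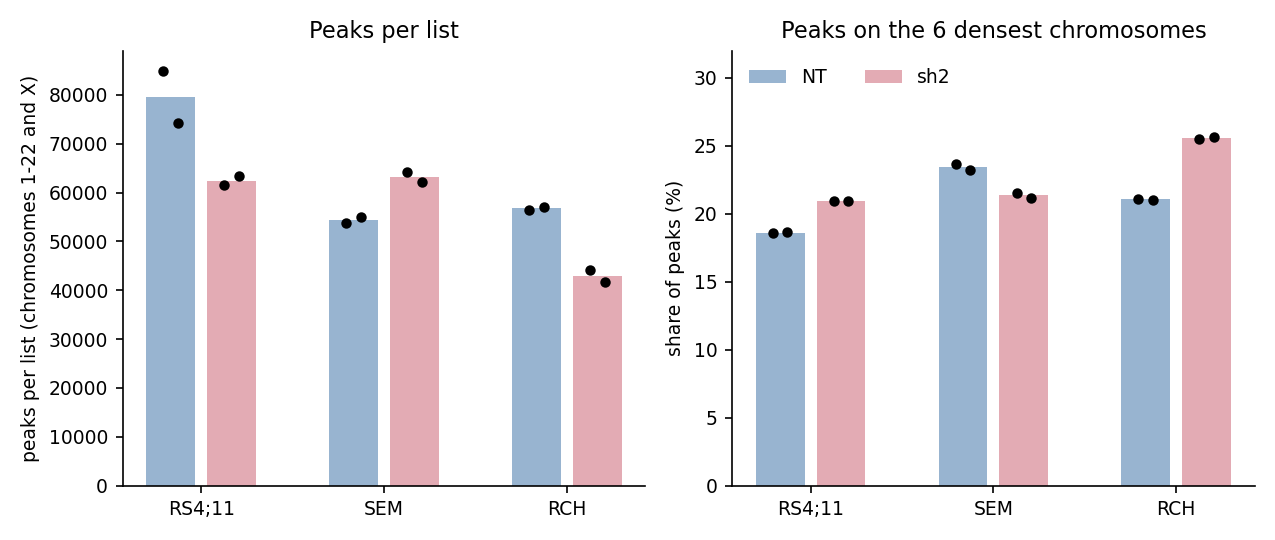
Left, number of peaks per list on chromosomes 1-22 and X. Right, percentage of those peaks on the 6 chromosomes with the most regions open in all 12 lists per Mb. Bars are means of 2 libraries, points are the libraries, blue is NT and red is sh2. Peak number rose in SEM and fell in the other lines, and the share on the dense chromosomes moved the opposite way in each line.

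The share of a list's peaks that lay on single chromosomes also differed between NT and sh2. On chromosome 19, among the most gene-dense human chromosomes, the share of all peaks rose from 2.06% to 2.74% in RS4;11 and from 3.04% to 4.74% in RCH, and fell from 3.71% to 3.06% in SEM. On chromosome 4, which is gene-poor, it fell from 6.94% to 5.95% in RS4;11 and from 5.79% to 4.56% in RCH, and rose from 5.45% to 6.07% in SEM. Chromosome X followed chromosome 4, with 3.80% and 3.35% in RS4;11, 3.08% and 2.67% in RCH, and 2.88% and 3.32% in SEM for NT and sh2. Chromosomes were ranked by the number of regions open in all 12 lists per Mb. Length was the full hg19 length, unassembled sequence included, so chromosomes with large gaps rank too low. Chromosome 22, at 7.56 per Mb, was not among the 6 densest. Chromosome 9 was among the 6 sparsest at 6.05, against 6.18 on chromosome 15, and holds a stretch without RS4;11 peaks described below. Over the 6 densest (11, 12, 16, 17, 19 and 20), the share changed by 2.34 percentage points in RS4;11, by 4.50 in RCH and by -2.10 in SEM. The number of peaks there moved like the total but by less. It changed by -11.5% in RS4;11 against -23.7% on the other chromosomes, by -8.30% against -28.7% in RCH and by 5.74% against 19.3% in SEM. The 2 libraries of a sample differed by at most 0.462 points in this share.

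Lists overlapped most within a sample, less between NT and sh2 of a line, and on average least between lines. The Jaccard index, the bases shared by a pair of lists over the bases covered by either, averaged 0.681 between libraries of a sample in RS4;11, 0.664 in SEM and 0.606 in RCH. Between NT and sh2 of a line it averaged 0.614, 0.608 and 0.521, and every one of these pairs lay below both pairs from the same samples. Since NT and sh2 are also different samples, the lower overlap cannot be credited to the knockdown. Lists of different lines averaged 0.465, with single pairs up to 0.536, above the NT to sh2 pairs of RCH (0.514 to 0.530). Among NT lists, the index was 0.478 for RS4;11 and SEM, which share their fusion, 0.449 for RS4;11 and RCH, and 0.471 for SEM and RCH.

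**Figure D2:**
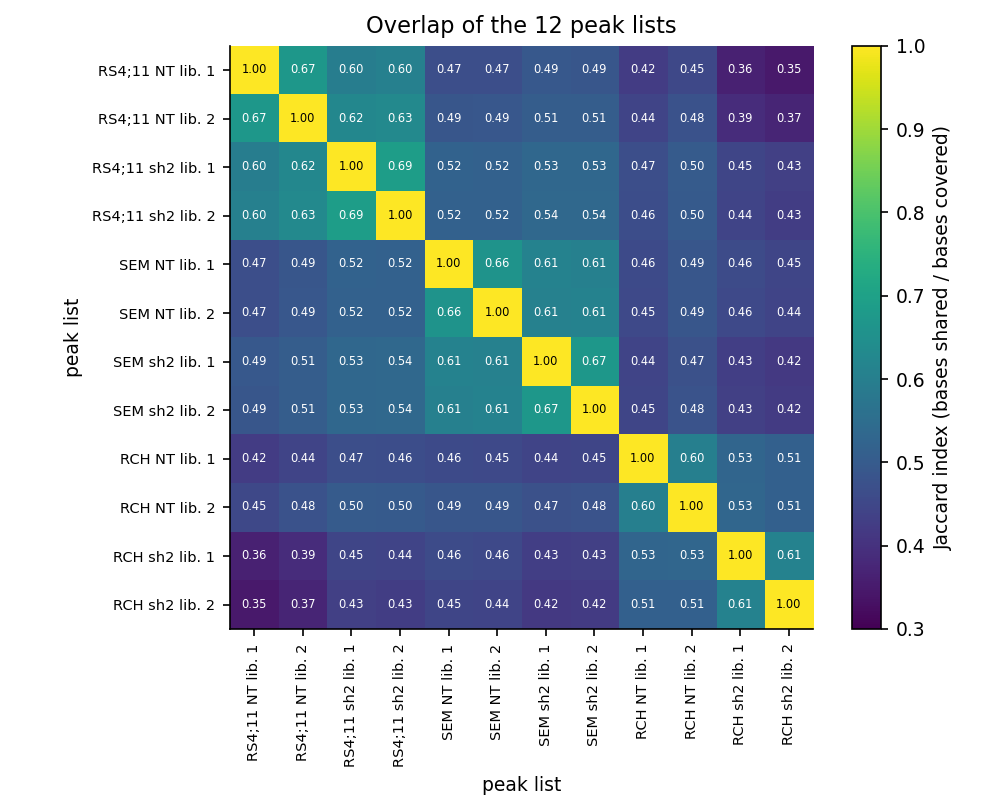
Jaccard index of each pair of the 12 peak lists, in bases shared over bases covered by either. Lists of a line overlap more on average than lists of different lines. The NT to sh2 pairs of RCH (0.514 to 0.530) nevertheless lie below the highest pair of different lines (0.536). Within each line the 2 libraries of a sample overlap more (0.606 to 0.681 on average) than NT and sh2 (0.521 to 0.614).

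Regions open in only NT or only sh2 were then counted in each line. A region was NT-only where both NT libraries and no sh2 library had a peak, and sh2-only in the reverse case. RS4;11 had 9519 NT-only and 864 sh2-only regions among 98313. RCH had 8030 and 1476 among 76823. SEM had 2101 and 6164 among 80589. The sh2-only share of these changed regions was 8.32% in RS4;11 (exact 95% binomial interval 7.80 to 8.87), 15.5% in RCH (14.8 to 16.3) and 74.6% in SEM (73.6 to 75.5). When the 4 lists of a line were regrouped with 1 NT and 1 sh2 library on each side, at most 1921 regions in RS4;11, 1201 in RCH and 1237 in SEM were open on 1 side only. The smaller class of RS4;11, at 864, lay below that limit. The split moved when 1 library was left out. Without sh2 library 1, RS4;11 had 12664 NT-only and 4236 sh2-only regions. Without sh2 library 2, RCH had 10524 and 5890, and without NT library 1, SEM had 6198 and 9302. Peaks in all 4 lists were found at 47362 regions in RS4;11 (48.2%), 37991 in SEM (47.1%) and 28465 in RCH (37.1%), and apart from the changed regions the rest differed between the 2 libraries of at least 1 sample. Changed regions were weaker, with a median fold enrichment (the authors' value per peak) of 5.23 for NT-only regions of RS4;11 against 9.19 in NT libraries at regions open in all 4 lists.

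The balance of the 2 classes depended on the length of the lists. With every list of a line reduced to the same number of peaks of highest fold, RS4;11 had 5184 NT-only and 3174 sh2-only regions, RCH 4083 and 3184, and SEM 3761 and 4465. The sh2-only share became 38.0%, 43.8% and 54.3%. In cut lists a class means that no peak of the other condition remained after the cut, and a weaker deposited peak can lie there. The rise of sh2-only regions from 864 to 3174 in RS4;11 and from 1476 to 3184 in RCH came with the cutting of the NT lists. The side with more regions stayed the same in each line, and the changed regions outnumbered those of the larger crossed split by 4.23, 4.15 and 4.11 times.

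Which way regions changed depended on the chromosome. With lists of equal length, 92.4% of the changed regions of chromosome 19 were sh2-only in RS4;11 (interval 87.6 to 95.8) and 94.99% in RCH (92.2 to 97.0), against 10.1% in SEM (6.28 to 15.2). With such lists sh2-only means that no NT peak remained after the cut, not that none was called. In the same order of lines, chromosome 22 had 78.8%, 92.4% and 7.77%, and chromosome 17 had 76.3%, 82.0% and 13.3%. Chromosome 4 gave 19.7%, 16.2% and 67.2%, and chromosome 13 gave 28.2%, 18.8% and 72.6%. Chromosome X gave 25.6%, 26.3% and 77.5%. With the lists as deposited, chromosome 19 gave 63.9%, 80.0% and 33.1% in the same order, chromosome 22 gave 27.3%, 73.9% and 34.1%, and chromosome 17 gave 32.9%, 51.2% and 30.7%. In RS4;11 every chromosome but 19 then had more NT-only than sh2-only regions. Chromosome 4 gave 2.40%, 2.78% and 83.3% as deposited.

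Across the 23 chromosomes, the rank correlation (Spearman's rho) of the sh2-only share with the density of regions open in all 12 lists was 0.685 in RS4;11, 0.608 in RCH and -0.587 in SEM. Chromosomes are not independent replicates. In 1000 shuffles of the NT-only and sh2-only labels over the changed regions, which treat regions as independent, the size of rho stood at percentile 99.9, 99.6 and 99.3, below the highest shuffled values of 0.699, 0.659 and 0.679. With lists of equal length rho was 0.693, 0.748 and -0.605. Regions open in only 1 of the 2 libraries of a sample gave a rho of 0.542 (NT) and 0.535 (sh2) in SEM. In the other lines this was 0.134 and -0.019 (RS4;11) and -0.110 and -0.187 (RCH). In SEM the size of rho alone therefore does not set NT against sh2 apart from libraries of a sample. Between the 6 densest and the 6 sparsest chromosomes the odds ratio for a changed region to be sh2-only was 4.99 in RS4;11, 5.65 in RCH and 0.347 in SEM. As deposited, the sh2-only share on the dense chromosomes was 19.2%, 35.8% and 60.8%, against 4.54%, 8.998% and 81.7% on the sparse ones, so that the larger class was that of the whole line on both. With equal lists the dense chromosomes had 59.97%, 70.6% and 35.5% and the sparse ones 28.6%, 27.3% and 65.7%.

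**Figure D3:**
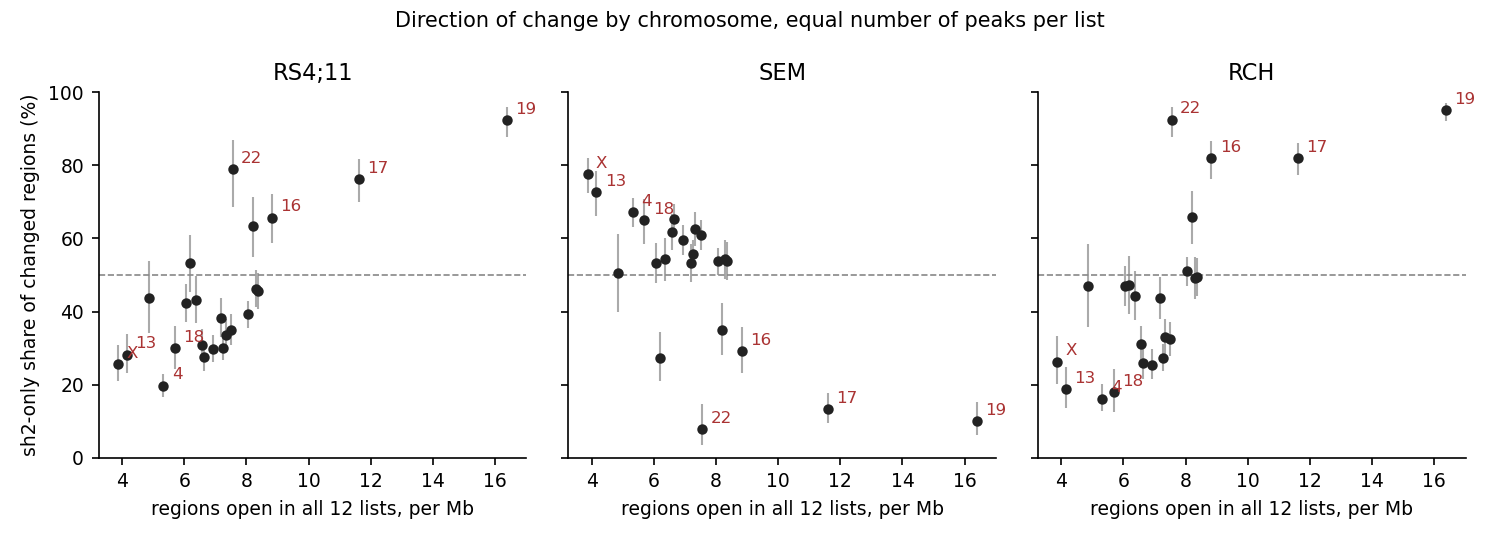
Share of changed regions that were sh2-only (%) on each chromosome, against the number of regions open in all 12 lists per Mb, with an equal number of peaks per list. A region is sh2-only here if no NT peak remained after lists were cut, and a weaker NT peak may have been called there. Points are chromosomes, bars are exact 95% binomial intervals and the dashed line marks 50%. The share falls with density in SEM, to 10.1% on chromosome 19, and rises in the other lines, to 92.4% and 94.99%.

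At a finer scale, changed regions were counted in bins of 1 Mb with at least 10 of them. The bin at 2 to 3 Mb of chromosome 19 stood out in opposite directions, with 9 NT-only regions and 1 sh2-only region in SEM and 10 sh2-only regions and 1 NT-only region in RCH. In RCH the bins at 64 to 65 Mb of chromosome 11 (8 sh2-only, 2 NT-only) and at 139 to 140 Mb of chromosome 9 (8 and 3) also passed the limit drawn from shuffled regions. In all, 8 of 28 bins passed in RCH, 1 of 13 in SEM and 0 of 93 in RS4;11. Even bins made up wholly of a line's larger class did not pass. These held 16 NT-only regions of 16 in RS4;11, 12 of 12 in RCH and 12 sh2-only regions of 12 in SEM. The counts therefore bear on the smaller class only, and 0 of 93 does not show that RS4;11 was evenly balanced. With lists of equal length, 34 of 43 bins passed in RCH, 9 of 13 in SEM and 8 of 21 in RS4;11.

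Regions were also placed by their distance to the nearest region open in all 8 lists of the other lines. In RS4;11, NT-only regions lay at a median of 81.8 kb and sh2-only regions at 16.8 kb, and 43.8% against 9.38% lay more than 100 kb away. NT-only regions were the farther class on all 23 chromosomes. In RCH the medians were 22.2 and 12.1 kb, the shares beyond 100 kb were 21.3% and 7.72%, and NT-only regions were farther on 21 chromosomes. In SEM the medians were 30.24 and 30.15 kb, with shares of 24.4% and 21.7%, and NT-only regions were farther on 15 chromosomes and sh2-only regions on 8. With lists of equal length the SEM medians were 15.9 kb for NT-only and 35.2 kb for sh2-only regions, and sh2-only regions were farther on 19 of 23 chromosomes. The order in SEM thus turned with the length of the lists, while in the other lines NT-only regions were farther under both settings.

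**Figure D4:**
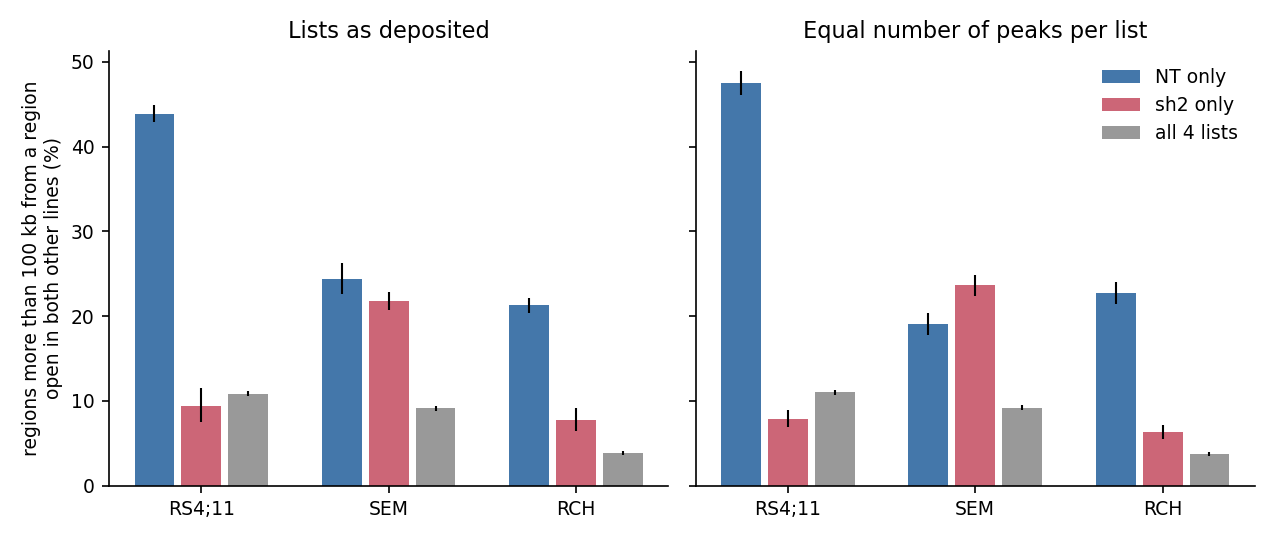
Percentage of regions more than 100 kb from the nearest region open in all 8 lists of the other lines, for NT-only regions, sh2-only regions and regions open in all 4 lists of a line. Bars are shares and lines exact 95% binomial intervals. In SEM, sh2-only regions are the farther class only with equal lists, and in the other lines NT-only regions are farther under both settings (43.8% against 9.38% and 21.3% against 7.72% as deposited).

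The last comparison asked which regions changed the same way in several lines. Over all lists, 130872 regions were formed and 21535 were open in all 12. NT-only regions were found in 3 lines at 77 places, and sh2-only regions at 0 places, or 45 and 1 with lists of equal length. In at least 2 lines there were 1381 NT-only and 115 sh2-only regions, against 809 and 340 with equal lists. These counts moved with single libraries. The sh2-only count in at least 2 lines was 166 to 293 with 1 library left out, over 1.5 times the full count without any library but those of RCH NT, and highest without RS4;11 NT library 1. The NT-only count in at least 2 lines was 2203 without RCH NT library 1, and that in 3 lines was 122 and 129 without SEM NT library 1 and 2. The sh2-only count in 3 lines was 0 to 3. With the stricter fold, NT-only counts were 690 and 31. Without the pairing by line, 1784 regions had a peak in at least 4 more NT than sh2 libraries and 163 in at least 4 more sh2 libraries. The excess of NT-only regions in at least 2 lines follows in part from the larger NT-only classes of RS4;11 and RCH. If these lines changed independently over the 54179 regions open in both, 390 would be NT-only in both and 5.34 sh2-only in both. Found were 1016 and 27. Such an excess alone does not show a shared direction. Regions sh2-only in SEM and NT-only in RCH also exceeded their expected number (373 against 230). Opposite changes of RS4;11 and RCH fell below theirs (20 against 39.0 and 46 against 53.4). The planned expected number over all lines is not given here.

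The 3 regions lost in all lines with the highest fold enrichment lay on chromosome 14 from 44510899 to 44511303, on chromosome 9 from 122225576 to 122226168 and on chromosome 7 from 46214733 to 46215318. The chromosome 14 region had folds of 10.4 and 11.7 in RS4;11 NT, 7.05 and 6.25 in SEM NT and 10.2 and 8.41 in RCH NT, and no peak in any sh2 list. The chromosome 9 region had folds of 12.5 and 11.8, 8.44 and 6.16, and 8.62 and 6.47 in the NT libraries of these lines. The chromosome 7 region had 11.99 and 14.5, 7.91 and 5.46, and 7.37 and 7.02.

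The 3 highest-ranked regions lost in at least 2 lines were lost in RS4;11 and RCH. Their mean fold percentiles were 88.6 to 89.8, against 67.6 to 70.6 for the 3 regions lost in all lines. They were picked from 1381 regions and the latter from 77, so this does not show a stronger class. The first lay on chromosome 14 from 41951653 to 41952490, with folds of 16.9 and 12.6 in RS4;11 NT and 11.9 and 11.4 in RCH NT. SEM kept a peak there in all lists, with 9.29 and 12.8 with NT and 6.52 and 4.92 with sh2. The region on chromosome 12 from 103849083 to 103849526 was alike, with 16.99 and 10.9 in RS4;11 NT, 11.7 and 12.1 in RCH NT, 10.7 and 10.2 in SEM NT and 5.46 and 5.67 in SEM sh2. The region on chromosome 13 from 61890663 to 61891129 had 15.5 and 14.1 in RS4;11 NT and 11.3 and 10.6 in RCH NT, and no peak in SEM.

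The 3 sh2-only regions ranked highest had mean fold percentiles of 57.4 to 67.5, and each was found in 2 lines. The 3 highest NT-only regions in at least 2 lines had 88.6 to 89.8. Since these were picked from 1381 regions and the sh2-only ones from 115, a lower maximum does not show a weaker class. The region on chromosome 10 from 26014885 to 26015213 had folds of 9.56 and 10.2 in SEM sh2 and 5.07 and 6.72 in RCH sh2, and RS4;11 had a peak there in NT library 2 (4.98) and in both sh2 libraries (8.17 and 6.21). On chromosome 18 from 2104716 to 2105202 they were 7.73 and 8.60 in SEM sh2 and 5.63 and 5.49 in RCH sh2, and RS4;11 was open there in all 4 lists. On chromosome 1 from 29456433 to 29456829 they were 8.97 and 8.13 in RS4;11 sh2 and 6.10 and 7.23 in SEM sh2, and RCH had no peak.

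RS4;11 and RCH changed together. Of 1109 regions that changed in both, 1043 changed in the same direction and 66 in opposite directions, with an odds ratio of 29.5 (95% interval 14.8 to 60.1). With equal lists it was 675 of 747, with an odds ratio of 80.8 (48.7 to 138.3). When regions were compared only within a chromosome and within 1 of 3 classes of distance to regions open in the third line (up to 10 kb, up to 100 kb and beyond), the odds ratio was 8.07 as deposited and 45.8 with equal lists. SEM and RCH changed in opposite directions at 411 of 679 shared regions, with an odds ratio of 0.733 (0.452 to 1.19), which became 0.233 (0.161 to 0.334) with equal lists. Within the same classes it was 0.973 and 0.262. For RS4;11 and SEM the odds ratio was 2.83 (1.51 to 5.58) as deposited and 0.703 (0.510 to 0.966) with equal lists. Within the same classes it was 4.66 and 1.11, so that the turn seen without them was absent.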

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

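The tests of explanations in this part were chosen after the results had been seen.

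Peak number moved one way in SEM and the other way in the remaining lines, with every library of sh2 beyond every library of NT. The log2 ratio of sh2 over NT was -0.35 in RS4;11, 0.22 in SEM and -0.40 in RCH, and the difference between lines was not tested. If depth set the number of peaks, the background level should move with it. In RCH the background level rose (log2 0.53) while peaks fell, which argues against depth there only if the level tracks depth. That requires fragments extended alike, which is unknown. Level and peak number also did not always move together between the 2 libraries of a sample, as in SEM NT. Depth is therefore not excluded in RCH. The median fold of RCH also fell (6.10 to 5.37), and weaker enrichment was not separated from the knockdown. In RS4;11 (-0.21) and SEM (0.18) the background moved with the peaks, so depth and knockdown cannot be told apart in these lines.

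The share of peaks on the 6 densest chromosomes changed by 2.34 percentage points in RS4;11, -2.10 in SEM and 4.50 in RCH, again untested between lines and with all libraries apart. The trend by chromosome stayed with equal lists, so the number of peaks alone does not account for it in RS4;11 and RCH. The weakest rank correlation was then -0.605, in SEM, which in size only just exceeded the highest shuffled value of 0.604, too little to decide there. Cutting lists by fold does not equalize signal over background, so a cause that left the lists unequal is not excluded in any line. Differences between libraries of a sample reached 0.462 points, under the smallest change of 2.10, although in SEM the 2 libraries of each sample also differed along the density of chromosomes, with rank correlations of 0.542 (NT) and 0.535 (sh2). Copy number that the NT and sh2 samples of a line share cannot by itself set them apart. A copy number of whole chromosomes that differed between them was not measured and stays open in every line. With equal lists 1 class lay farther from shared open regions on 23 of 23 chromosomes in RS4;11 and in RCH and on 19 in SEM. An order within chromosomes can stand beside copy number, however, and decides nothing about a trend between them. With 1 sample per line and shRNA, preparation, including signal over background and GC content, cannot be told apart from the knockdown, and neither GC nor a difference between the lines in their response was tested.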

How the results depend on the processing

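Alternatives were fixed before the data were examined, except those on the rank correlation with chromosome density and on line-specific regions, and equal lists for bins, distances and odds ratios, which were chosen after seeing the data. Over 113 alternatives other than leaving out a library, 67 values stayed within the spread or within 1.5 times the main count, 44 moved and 2 reversed. Leaving out 1 library gave 79, 53 and 0 of 132. Causes of the moves were not tested, except that leaving out a library loosens the rule by construction (1 list in place of 2 on a side), which raises the counts. Promoter, annotation, gene list and motif alternatives were not run. Depth is unknown, so regions near the detection limit may be missed in the libraries with less signal.

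With an equal number of peaks per list, NT-only and sh2-only regions were 5184 and 3174 in RS4;11, 3761 and 4465 in SEM, and 4083 and 3184 in RCH. The log2 of sh2-only over NT-only was then -0.71, 0.25 and -0.36. Regions NT-only in 2 or 3 lines were 809 and sh2-only 340, and in 3 lines 45 and 1. The rank correlation was -0.605 in SEM and 0.748 in RCH. The share of regions beyond 100 kb (NT-only minus sh2-only) reversed in SEM, from 2.68 to -4.56 percentage points, as did the log2 odds ratio of RS4;11 with SEM without classes of chromosome and distance, from 1.499 to -0.51. The cause was not tested.

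With the stricter fold, log2 peak number was 0.28 in SEM and -0.74 in RCH, and log2 covered length 0.18 and -0.62. The log2 ratio of median width, -0.01 in RS4;11, -0.07 in SEM and 0 in RCH as deposited, was -0.077, -0.14 and 0.19, and with regions in both libraries of a sample -0.036 in RS4;11 and -0.11 in SEM. NT-only regions were 4712 in RS4;11 and 1054 in SEM, sh2-only regions 4063 in SEM and 299 in RCH, where the log2 of sh2-only over NT-only was -4.38. Across lines NT-only regions were 690 in 2 or 3 lines and 31 in 3. The rank correlation was -0.75 in SEM and 0.567 in RCH. By share of peaks overlapped by at least 50%, the difference in overlap in RCH was 0.0693. Bins of 5 Mb off balance were 2.91% in RS4;11 and 7.92% in RCH.

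Leaving out 1 library in turn, NT-only regions were 12664 to 23285 in RS4;11 (highest without NT library 2), 3474 to 6198 in SEM (without NT library 1) and 10524 to 17547 in RCH (without NT library 1). The sh2-only regions were 1625 to 4236 in RS4;11 (highest without sh2 library 1), 9302 to 13134 in SEM (without sh2 library 2) and 2680 to 5890 in RCH (without sh2 library 2). The log2 ratios were -3.84 to -1.58, 0.59 to 1.92 and -2.71 to -0.84. Across lines, NT-only regions were 1523 to 2203 and sh2-only regions 166 to 293 in 2 or 3 lines, and 82 to 129 and 0 to 3 in 3 lines. Rank correlations were 0.638 to 0.703 in RS4;11, -0.594 to -0.569 in SEM and 0.620 to 0.675 in RCH. Without the replicate block (pairing by line) the counts were 1784 NT-only and 163 sh2-only, and no other result was run without it.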

Other observations

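The tests in this part were chosen after the values had been seen, except for the splits of the samples, which were planned but whose reading was set down afterwards.

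Regions open in all 4 lists of 1 line and closed in the other lines numbered 2659 in RS4;11, 1253 in SEM and 1163 in RCH, or 1243, 1103 and 1345 with an equal number of peaks in all lists. RS4;11 and SEM, which share a fusion, had 1887 regions open in both and closed in RCH, against 558 for RS4;11 with RCH and 465 for SEM with RCH. With equal numbers these were 922, 495 and 541. Enrichment by chromosome is given for the lists as deposited only. Those of RS4;11 NT were the longest, so list length was not separated from it. Regions open only in RS4;11 were most enriched on chromosome 13 (2.07 times their share of all regions) and least on chromosome 19 (0.158). Regions open only in RCH were most enriched on chromosome 19 (2.27) and least on X (0.407). The set open in SEM and RCH and closed in RS4;11 was most enriched on chromosome 19 (3.43) and then on chromosome 9 (2.47), where the bin from 21 to 22 Mb held 15 of its regions.

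That bin lies in a stretch of chromosome 9, from 19925993 to 24699454, in which 26 consecutive regions open in all 8 lists of SEM and RCH were absent from RS4;11, and the 4 RS4;11 lists had 0 peaks. No RS4;11 peak lay between 19856955 and 25134360, a gap of 5.28 Mb. The other lines had 639 peaks there, 418 of them outside the 26 regions, for which 273.0 were expected in RS4;11 from the list totals. The next longest run in RS4;11 held 5 regions, and the longest in 1000 shuffles of absent regions held 4, so scattered loss of single regions does not account for it. Loss of the DNA in RS4;11 is a candidate explanation, since 0 peaks is what it predicts, although a closed domain would look the same in peak lists. The stretch is present with NT and with sh2, so it is no part of the knockdown comparison.

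NT-only or sh2-only regions shared by all lines numbered 77. Over the 10 splits of the 6 samples into 3 and 3, 7 gave at least as many, the real one included, and the highest other gave 661. With 10 splits a share under 0.05 is out of reach. Splits that keep both samples of some line together all gave more, from 147 to 661. Each sets both samples of 1 line against both of another, so it also counts regions that differ between lines. The 7 of 10 therefore decides nothing about NT against sh2. Among splits that part every line, the real one gave 77 and the others 30, 6 and 1.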
